A study of Homo sapiens with 12 samples.

How the data were processed

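Gene expression in MDA-MB-231 cells was measured on Affymetrix human expression arrays, one per culture, after 24 h with DMSO, 5 uM SAHA, 2.5 mM pargyline or both drugs, with 3 biological replicates in each of 4 groups. Total RNA had been extracted with an RNeasy kit and DNase, and biotin-labelled RNA made with a MessageAmp Premier kit. The deposited values of the 12 arrays are log2 intensities that the authors made with an RMA-type method; the notes name RMA but give no software version, and do not say whether the 12 arrays were normalized together. The values were used as deposited, with no further background correction, scaling or filter in the values reported. For arrays, the number of replicates limits the precision.

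The array holds 22277 probe sets, of which 62 are controls, 19064 are listed for 1 gene, 1043 for several genes and 2108 for none. Gene symbols were updated by gene identifier with the RefSeq gene table of assembly GRCh38.p14. The tests used 11963 genes, each by the probe set with the highest mean log2 value over the 12 arrays; 4310 genes had more than 1 probe set, and values of the others are given for some of the genes named. Probe sets with several or no genes were tested apart and are given as counts. No positions are given, since no probe positions with a stated genome build were at hand.

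A linear model with a mean for each group was fitted to all 12 arrays, with 8 residual degrees of freedom, in limma 3.58.1 under R 4.3.3 (lmFit and eBayes). The 7 comparisons were each drug and the combination against DMSO, the combination against each drug, SAHA against pargyline, and the interaction, which is the combination effect minus the sum of the single-drug effects. A gene passed, and is said to have risen or fallen, with a Benjamini-Hochberg adjusted p under 0.05 over all genes in limma's moderated test, two-sided. Errors of log2 fold changes are standard errors from this model. Differences in array quality were tested with exact two-sided permutation tests.

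In all, 31 gene lists with 1066 entries, 930 of them measured, were written before the data were examined, as were the comparisons, the thresholds and the rule for naming genes. They cover the drugs' targets and partners, histones, growth arrest, DNA replication, mitosis, DNA repair, apoptosis regulators, cholesterol synthesis, fatty acid synthesis, endoplasmic reticulum chaperones, ATF4 targets, heat shock, metallothioneins, oxidative stress, xenobiotic response, hypoxia and glycolysis, oxidative phosphorylation, ribosome biogenesis, epithelial, mesenchymal, neuronal, germline, interferon-stimulated, antigen presentation, inflammatory, immediate early and MAPK response, lysosome and autophagy, luminal breast, basal or myoepithelial, fibroblast and leukocyte genes. Each list was tested against all other genes with limma's camera at its preset inter-gene correlation of 0.01, adjusted over the 31 lists of a comparison. The same test with a correlation estimated from the data is given beside each list that passed, and fry, a rotation test of whether a list moves on balance one way, was run as an alternative. Counts of list members are given over all genes tested and adjusted over the list alone.

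Genes were named by rule: in each comparison with DMSO the 8 largest rises and 8 largest falls, and in the other comparisons the 5 largest each way, among genes that passed, whose groups did not overlap (not asked for the interaction) and whose highest group mean was above 7.06, the median over genes of the mean log2 value. In addition up to 4 members of each list that passed and lay above that level could be named, and HDAC1 to HDAC11, KDM1A, MAOA, MAOB and CDKN1A in any case. Exceptions are said to have been named after their values were seen. The comparison of SAHA with pargyline was given list members alone.

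Alternatives were quantile normalization, centring each array on its median, leaving out dim genes (those below the lower tertile or below the median of the mean value), the mean of all probe sets of a gene or every probe set on its own, replicate number as a block, array weights, a trended and robust prior, a fit of the compared groups alone, an adjusted p under 0.01, a change of at least 2-fold, fry or an estimated correlation for lists, and leaving out each array in turn. The labels do not say whether equally numbered replicates share a culture date, so the block is an alternative. Other splits of the arrays were fitted in the same way, all 10 for each pair of groups and 100 drawn for the interaction. For the interaction, residuals of a model without it were also put back in 99 other orders of the arrays. The procedure was tested on simulated data in which 200 genes were changed: of genes changed 2-fold, 89.4% were recovered for SAHA against DMSO, 87.9% for pargyline against DMSO and 86.4% for the interaction, and of those changed 1.41-fold, 61.8%, 77.9% and 50%.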

Results

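RNA from MDA-MB-231 cells, an established human triple-negative breast cancer line with mesenchymal features, was measured on 12 expression arrays. The cells had been treated for 24 h with the vehicle DMSO, with 5 uM SAHA (vorinostat, an inhibitor of histone deacetylases), with 2.5 mM pargyline, or with both drugs. Pargyline is a monoamine oxidase inhibitor that can also inhibit the histone demethylase LSD1, which is encoded by KDM1A. Each of the 4 groups held 3 biological replicates. Each array gave log2 values for 22277 probe sets, and 11963 genes were tested, each by its brightest probe set. The median over genes of the standard error of a difference between groups was 0.077 on the log2 scale, and the number of arrays limits this precision.

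Array medians lay between 5.15 and 5.38 on the log2 scale, and replicates correlated with r between 0.998 and 0.999 across probe sets. The difference between the 3' and 5' actin controls averaged 0.79 ± 0.03 (SD, n = 3) with DMSO, 0.84 ± 0.07 with SAHA, 0.80 ± 0.17 with pargyline and 0.89 ± 0.05 with both drugs. In exact two-sided permutation tests against DMSO these gave p = 0.3, 0.8 and 0.1, where 0.1 is the smallest p that 3 arrays against 3 can give. The poly-A RNA added to each sample read 0.28 higher with SAHA, 0.33 higher with both drugs, and differed by -0.28 with pargyline (exact p = 0.1, 0.2 and 0.2). No adjusted p among the 15 array quality tests was below 0.5.

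SAHA was compared with DMSO to ask what an HDAC inhibitor changed on its own. It raised 2754 genes and lowered 2768 of the 11963, and 1123 rose and 1047 fell by at least 2-fold. HPCAL4, a neuronal calcium sensor, rose by 7.66 ± 0.10 (log2 fold change ± SE, n = 3 arrays per group), ABAT, the enzyme that breaks down the transmitter GABA, by 7.15 ± 0.15, and ENPP2, which makes the lipid signal lysophosphatidic acid, by 6.55 ± 0.27. The largest falls were in the collagen chaperone gene SERPINH1 (-7.74 ± 0.26), the organic anion transporter gene SLCO4A1 (-6.98 ± 0.22) and the interferon-induced antiviral gene IFIT3 (-6.82 ± 0.15). The other largest rises were in CRISPLD2 (6.27 ± 0.36), the secretory granule gene SCG2 (6.10 ± 0.13), the fatty acid carrier FABP4 (6.07 ± 0.32), the dehydrogenase DHRS2 (6.01 ± 0.15) and the lysosomal membrane gene LAMP3 (5.86 ± 0.13). Falls of similar size were in LPXN (-5.81 ± 0.28), the cytokine receptor IL7R (-5.77 ± 0.65), the coagulation inhibitor TFPI (-5.56 ± 0.26), the urokinase gene PLAU (-5.43 ± 0.65) and the desmosome gene PKP3 (-5.32 ± 0.19). Adjusted p among these 16 genes ran from 5.92e-11 to 6.63e-05 in limma. A further probe set listed for HPCAL4 gave 0.27, 1 of the further probe sets listed for ABAT gave 0.04, and 1 for PKP3 gave -1.76.

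Genes of cell division were lower as sets with SAHA. Of 50 mitosis genes, 43 fell, 0 rose and 7 did not pass (the same adjusted over the list alone). They gave adjusted p = 9.13e-12 in camera, and adjusted p = 0.502 with an estimated correlation. PLK1, a kinase that drives mitotic entry, fell by 4.26 ± 0.26, KIF20A changed by -2.40 ± 0.23 and the transcription factor FOXM1 by -2.32 ± 0.15. Of 40 DNA replication genes, 24 fell, 4 rose and 12 did not pass (25 fell and 5 rose adjusted over the list alone). In camera adjusted p was 0.000192, and adjusted p = 0.759 with an estimated correlation. GINS3 (-2.11 ± 0.15) and E2F8 (-1.66 ± 0.14) were among the falls. Growth arrest genes moved the other way. Of 21 growth arrest genes, 11 rose, 1 fell and 9 did not pass (the same adjusted over the list alone). Camera gave adjusted p = 0.00692, and adjusted p = 0.38 with an estimated correlation. CDKN1A, which encodes the cell cycle inhibitor p21, rose by 3.82 ± 0.25, TXNIP by 3.35 ± 0.19 and the inhibitor gene CDKN1C by 2.89 ± 0.33. Of 28 ribosome biogenesis genes, 18 fell, 4 rose and 6 did not pass (18 fell and 5 rose adjusted over the list alone). Their adjusted p was 0.000274 in camera, and adjusted p = 0.502 with an estimated correlation. UTP20 (-2.52 ± 0.18) and NIP7 (-1.40 ± 0.06) were among the falls, while MYC, a driver of this programme, rose by 1.51 ± 0.22.

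Other groups were higher as sets with SAHA. Of 20 histone genes, 11 rose, 2 fell and 7 did not pass (the same adjusted over the list alone). Adjusted p in camera was 0.014, and adjusted p = 0.759 with an estimated correlation. H2BC5 (2.95 ± 0.18), H4C8 (2.25 ± 0.16) and the linker histone gene H1-10 (2.12 ± 0.17) were among the rises. Of 10 metallothionein and zinc response genes, 8 rose, 0 fell and 2 did not pass (the same adjusted over the list alone). The list gave adjusted p = 0.000347 in camera, and adjusted p = 0.38 with an estimated correlation. MT1F (1.37 ± 0.09) and the zinc exporter SLC30A1 (1.05 ± 0.06) were among them. Probe sets of histones and of metallothioneins can bind transcripts of close relatives. Of 45 lysosome and autophagy genes, 28 rose, 7 fell and 10 did not pass (30 rose and 7 fell adjusted over the list alone). They gave adjusted p = 0.000192 in camera, and adjusted p = 0.38 with an estimated correlation. The sialidase NEU1 (3.02 ± 0.31) and the autophagy gene GABARAPL1 (2.70 ± 0.09) rose. Of 40 immediate early and MAPK genes, 22 rose, 9 fell and 9 did not pass (22 rose and 10 fell adjusted over the list alone). In camera adjusted p was 0.0141, and adjusted p = 0.38 with an estimated correlation. NR4A2 (4.92 ± 0.26) and FOS (4.42 ± 0.26) were among the rises. Of 20 cholesterol synthesis genes, 13 rose, 1 fell and 6 did not pass (the same adjusted over the list alone). Camera gave adjusted p = 0.0141, and adjusted p = 0.771 with an estimated correlation. The sterol reductase gene TM7SF2 (4.61 ± 0.25) and the regulator SREBF1 (3.16 ± 0.26) rose.

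The remaining SAHA groups held genes that went both ways. Of 41 interferon-stimulated genes, 19 fell, 7 rose and 15 did not pass (the same adjusted over the list alone). Their adjusted p was 0.0469 in camera, and adjusted p = 0.38 with an estimated correlation. IFIT2 (-5.12 ± 0.28) and IFI35 (-4.52 ± 0.14) fell, while IFI6, named after its value was seen, rose by 3.44 ± 0.12. Of 27 antigen presentation genes, 14 rose, 5 fell and 8 did not pass (the same adjusted over the list alone). Adjusted p in camera was 0.0454, and adjusted p = 0.502 with an estimated correlation. HLA-DMB rose by 5.24 ± 0.14, and the immunoproteasome subunits PSMB10 (-5.04 ± 0.15) and PSMB8 (-3.15 ± 0.31) fell. Of 31 oxidative stress genes, 16 rose, 7 fell and 8 did not pass (17 rose and 7 fell adjusted over the list alone). The list gave adjusted p = 0.0469 in camera, and adjusted p = 0.767 with an estimated correlation. BLVRB (2.14 ± 0.07) and the heme oxygenase gene HMOX1 (2.20 ± 0.35) rose, and the exporter ABCC3 (-2.6 ± 0.36) fell. Of 23 heat shock genes, 11 fell, 6 rose and 6 did not pass (12 fell and 6 rose adjusted over the list alone). They gave adjusted p = 0.0492 in camera, and adjusted p = 0.502 with an estimated correlation. Of 24 DNA repair genes, 13 fell, 3 rose and 8 did not pass (13 fell and 4 rose adjusted over the list alone). In camera adjusted p was 0.0469, and adjusted p = 0.759 with an estimated correlation. The small heat shock gene HSPB1 (-1.69 ± 0.11) and the repair gene BARD1 (-1.26 ± 0.10) fell.

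The calls on interferon-stimulated, heat shock and DNA repair genes with SAHA were lost with quantile normalization (adjusted p = 0.0599, 0.0773 and 0.0935). They were also lost with each array centred on its median (adjusted p = 0.278 for each), where the median gene lay at -0.10, 2385 genes were higher and 4070 lower, and that on DNA repair with replicate number as a block (adjusted p = 0.0791). Single arrays ended these calls too, with adjusted p from 0.0557 to 0.126: DNA repair and heat shock without DMSO replicate 1 or SAHA replicate 2 or 3, and interferon-stimulated without DMSO replicate 1 or 3 or SAHA replicate 2. Oxidative stress did not pass without SAHA replicate 1 or 3 (adjusted p = 0.0608 for each), nor antigen presentation without SAHA replicate 3 (adjusted p = 0.057). With array weights the DNA repair, heat shock, interferon-stimulated and oxidative stress calls were lost (adjusted p from 0.0538 to 0.0643), without genes below the lower tertile these and antigen presentation (0.0724 to 0.144), and without genes below the median also histone and immediate early genes (0.0557 to 0.353).

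Pargyline alone was compared with DMSO to ask what the monoamine oxidase and LSD1 inhibitor changed. It raised 1014 genes and lowered 891, and 231 rose but 42 fell by at least 2-fold. S100P, a calcium-binding protein gene, rose by 4.87 ± 0.47 (SE, n = 3 per group), ENPP2 by 4.57 ± 0.27, and ANGPTL4, an inhibitor of lipoprotein lipase, by 3.93 ± 0.28. The largest falls were in MYLIP (-2.92 ± 0.15), a ubiquitin ligase that degrades the low-density lipoprotein receptor, the cholesterol exporter ABCA1 (-2.22 ± 0.29) and TXNIP (-1.74 ± 0.19). The other largest rises were in the stress cytokine GDF15 (3.91 ± 0.56, with 0.00 from its further probe set), TM7SF2 (3.33 ± 0.25), KLHL24 (3.32 ± 0.32), ABCC3 (3.25 ± 0.36) and the secreted hormone gene STC1 (3.19 ± 0.42). The other largest falls were in REXO5 (-1.5 ± 0.16), the epithelial adhesion gene EPCAM (-1.32 ± 0.22), the clock gene PER2 (-1.30 ± 0.14, with -0.07 from its further probe set), PLK1 (-1.27 ± 0.26) and the centrosome gene CNTRL (-1.26 ± 0.16). Adjusted p among these 16 genes ran from 1.31e-05 to 0.0109 in limma.

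Lipid, hypoxia and stress response genes were higher as sets with pargyline. Of 20 cholesterol synthesis genes, 18 rose, 1 fell and 1 did not pass (the same adjusted over the list alone). Camera gave adjusted p = 1.37e-16, and adjusted p = 0.076 with an estimated correlation. HMGCS1, an early enzyme of the pathway, rose by 2.02 ± 0.29 and MSMO1 by 1.80 ± 0.19, while SREBF1, named after its value was seen, was the 1 that fell (-1.25 ± 0.26). Of 17 fatty acid synthesis genes, 9 rose, 0 fell and 8 did not pass (11 rose and 0 fell adjusted over the list alone). Their adjusted p was 5.40e-07 in camera, and adjusted p = 0.076 with an estimated correlation. ACSL1 (1.17 ± 0.19) and ACSL5 (0.93 ± 0.15), which activate fatty acids, rose. Of 35 hypoxia and glycolysis genes, 20 rose, 0 fell and 15 did not pass (22 rose and 0 fell adjusted over the list alone). Adjusted p in camera was 5.58e-16, and adjusted p = 0.0756 with an estimated correlation. The glycolytic enzyme gene ALDOC (2.34 ± 0.21), NDRG1 (1.80 ± 0.20) and PDK1 (1.71 ± 0.25) rose. ATF4 is a transcription factor of the amino acid and endoplasmic reticulum stress response. Of 35 ATF4 targets, 20 rose, 1 fell and 14 did not pass (23 rose and 1 fell adjusted over the list alone). The list gave adjusted p = 2.35e-15 in camera, and adjusted p = 0.0899 with an estimated correlation. CHAC1 (2.56 ± 0.50), ATF3 (2.39 ± 0.20) and DDIT4 (2.20 ± 0.14) rose. Of 26 endoplasmic reticulum chaperone genes, 9 rose, 0 fell and 17 did not pass (12 rose and 1 fell adjusted over the list alone). They gave adjusted p = 2.23e-06 in camera, and adjusted p = 0.0756 with an estimated correlation. DNAJB9 (1.08 ± 0.11) and XBP1 (0.97 ± 0.10) rose. Of 31 oxidative stress genes, 17 rose, 2 fell and 12 did not pass (18 rose and 2 fell adjusted over the list alone). In camera adjusted p was 1.74e-09, and adjusted p = 0.0899 with an estimated correlation. HMOX1 (2.62 ± 0.35) and AKR1C3 (2.53 ± 0.09), whose probe set can also bind transcripts of its close relatives, rose.

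Immune, lysosome, immediate early and growth arrest genes were higher as sets with pargyline. Of 41 interferon-stimulated genes, 10 rose, 0 fell and 31 did not pass (12 rose and 1 fell adjusted over the list alone; 11 rose and 7 fell with array centring, where the median of 0.25 became 0.12). Camera gave adjusted p = 2.45e-06, and adjusted p = 0.0418 with an estimated correlation. This was the 1 list call of any comparison that held with an estimated correlation. GBP2 (1.64 ± 0.22) and ISG20 (1.61 ± 0.25) rose. Antigen presentation genes had a median change of 0.01, or -0.12 with each array centred on its median. Of 27 antigen presentation genes, 9 rose, 0 fell and 18 did not pass (10 rose and 0 fell adjusted over the list alone). Their adjusted p was 0.000617 in camera, and adjusted p = 0.122 with an estimated correlation. HLA-B (0.65 ± 0.10), whose probe set can bind transcripts of related genes, and the peptide transporter TAP1 (0.62 ± 0.10) rose. Of 45 lysosome and autophagy genes, 18 rose, 2 fell and 25 did not pass (19 rose and 2 fell adjusted over the list alone). Adjusted p in camera was 1.48e-07, and adjusted p = 0.0756 with an estimated correlation. GABARAPL1 (1.93 ± 0.09) and the protease gene CTSD (1.31 ± 0.10) rose. Of 40 immediate early and MAPK genes, 12 rose, 2 fell and 26 did not pass (the same adjusted over the list alone). The list gave adjusted p = 0.000134 in camera, and adjusted p = 0.0756 with an estimated correlation. NR4A2 (2.24 ± 0.26) and the phosphatase gene DUSP1 (1.31 ± 0.14) rose. Growth arrest genes had a median change of 0.05, or -0.08 with array centring. Of 21 growth arrest genes, 6 rose, 2 fell and 13 did not pass (7 rose and 2 fell adjusted over the list alone). They gave adjusted p = 0.0251 in camera, and adjusted p = 0.252 with an estimated correlation. CDKN1A rose by 2.08 ± 0.25.

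Cell division, ribosome biogenesis and histone genes were lower as sets with pargyline. Of 50 mitosis genes, 23 fell, 0 rose and 27 did not pass (43 fell and 0 rose adjusted over the list alone). In camera adjusted p was 3.85e-14, and adjusted p = 0.246 with an estimated correlation. KIF20A (-1.09 ± 0.23) and CDC20 (-1.05 ± 0.17) fell. Of 40 DNA replication genes, 8 fell, 1 rose and 31 did not pass (11 fell and 1 rose adjusted over the list alone). Camera gave adjusted p = 4.18e-05, and adjusted p = 0.436 with an estimated correlation. POLE (-0.75 ± 0.10), a subunit of a replicative polymerase, fell. Of 24 DNA repair genes, 6 fell, 0 rose and 18 did not pass (8 fell and 1 rose adjusted over the list alone). Their adjusted p was 9.16e-05 in camera, and adjusted p = 0.161 with an estimated correlation. Of 28 ribosome biogenesis genes, 10 fell, 1 rose and 17 did not pass (11 fell and 2 rose adjusted over the list alone). Adjusted p in camera was 6.74e-06, and adjusted p = 0.161 with an estimated correlation. NPM3 (-0.99 ± 0.06) fell. Of 20 histone genes, 3 fell, 0 rose and 17 did not pass (the same adjusted over the list alone). The list gave adjusted p = 0.0258 in camera, and adjusted p = 0.474 with an estimated correlation. H1-2 (-1.14 ± 0.22) fell.

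Scaling moved the pargyline counts. Centring each array on its median put the median gene at -0.15 and gave 872 higher and 6168 lower genes (12.4% higher, against 53.2%). The histone call was lost with it (adjusted p = 0.105) and without DMSO replicate 3 (adjusted p = 0.0536) or pargyline replicate 1 (adjusted p = 0.0768), and with array weights (0.0871). The growth arrest call was lost without pargyline replicate 3 (adjusted p = 0.0699) and without genes below the lower tertile (0.0778) or the median (0.113). The 891 lower genes became 501 without DMSO replicate 1, 479 without DMSO replicate 2 and 549 without pargyline replicate 3. With replicate number as a block, 1207 genes were higher and 1121 lower.

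The combination was compared with DMSO to ask what both drugs did together. Both drugs raised 2903 genes and lowered 2872, and 1286 rose and 1168 fell by at least 2-fold. ABAT rose by 7.97 ± 0.15 (SE, n = 3 per group), HPCAL4 by 7.33 ± 0.10 and ENPP2 by 7.09 ± 0.27. The largest falls were in SERPINH1 (-8.41 ± 0.26), SLCO4A1 (-6.98 ± 0.22) and IL7R (-6.39 ± 0.65). The other largest rises were in NR4A1 (7.01 ± 0.56, with 0.00 and 1.39 from further probe sets), SCG2 (6.75 ± 0.13), the germ cell gene TEX14 (6.56 ± 0.21), CRISPLD2 (6.41 ± 0.36) and STC1 (6.21 ± 0.42). The other largest falls were in IFIT3 (-6.37 ± 0.15), LPXN (-5.78 ± 0.28), PLAU (-5.44 ± 0.65), the interferon pathway gene NMI (-5.43 ± 0.33) and PKP3 (-5.40 ± 0.19). Adjusted p among these 16 genes ran from 8.18e-11 to 5.69e-05 in limma.

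Of 50 mitosis genes, 49 fell, 1 rose and 0 did not pass (the same adjusted over the list alone). They gave adjusted p = 2.38e-16 in camera, and adjusted p = 0.343 with an estimated correlation. PLK1 (-5.20 ± 0.26), HMMR (-3.79 ± 0.34) and UBE2C (-3.07 ± 0.16) fell, and CKS2, named after its value was seen, was the 1 that rose (0.55 ± 0.11). Of 40 DNA replication genes, 33 fell, 2 rose and 5 did not pass (the same adjusted over the list alone). In camera adjusted p was 1.94e-08, and adjusted p = 0.343 with an estimated correlation. Of 24 DNA repair genes, 17 fell, 2 rose and 5 did not pass (the same adjusted over the list alone). Camera gave adjusted p = 0.000412, and adjusted p = 0.343 with an estimated correlation. RAD54L (-2.27 ± 0.22) and BARD1 (-2.05 ± 0.10) fell. Of 28 ribosome biogenesis genes, 19 fell, 2 rose and 7 did not pass (20 fell and 2 rose adjusted over the list alone). Their adjusted p was 0.000185 in camera, and adjusted p = 0.343 with an estimated correlation. Of 21 growth arrest genes, 12 rose, 2 fell and 7 did not pass (the same adjusted over the list alone). Adjusted p in camera was 0.00135, and adjusted p = 0.343 with an estimated correlation. CDKN1A rose by 4.90 ± 0.25.

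Cholesterol synthesis genes rose nearly as a whole with both drugs. Of 20 cholesterol synthesis genes, 19 rose, 1 fell and 0 did not pass (the same adjusted over the list alone). The list gave adjusted p = 6.19e-07 in camera, and adjusted p = 0.343 with an estimated correlation. INSIG1 (3.57 ± 0.30) and HMGCS1 (3.53 ± 0.29) rose, and ACAT2, named after its value was seen, was the 1 that fell (-0.78 ± 0.09). Of 17 fatty acid synthesis genes, 12 rose, 2 fell and 3 did not pass (the same adjusted over the list alone). This set gave adjusted p = 0.00512 in camera, and adjusted p = 0.343 with an estimated correlation. ACSL1 rose by 2.30 ± 0.19 and ACSL5 fell by 3.19 ± 0.15. Of 35 hypoxia and glycolysis genes, 19 rose, 6 fell and 10 did not pass (the same adjusted over the list alone). This set gave adjusted p = 0.000991 in camera, and adjusted p = 0.343 with an estimated correlation. The glucose transporter gene SLC2A3 (4.66 ± 0.15) rose. Of 45 lysosome and autophagy genes, 33 rose, 6 fell and 6 did not pass (34 rose and 6 fell adjusted over the list alone). This set gave adjusted p = 1.70e-07 in camera, and adjusted p = 0.273 with an estimated correlation. NEU1 rose by 3.96 ± 0.31. Of 40 immediate early and MAPK genes, 24 rose, 8 fell and 8 did not pass (24 rose and 10 fell adjusted over the list alone). These genes gave adjusted p = 0.00208 in camera, and adjusted p = 0.273 with an estimated correlation. FOS rose by 5.89 ± 0.26 and KLF2 fell by 3.33 ± 0.30.

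Endoplasmic reticulum chaperone genes (of 26, 16 rose and 6 fell), oxidative stress genes (of 31, 19 rose and 5 fell), histone genes (of 20, 11 rose and 3 fell), metallothionein and zinc response genes (of 10, 8 rose and 0 fell) and antigen presentation genes (of 27, 14 rose and 5 fell) were higher as sets. In the same order, 16, 20, 11, 8 and 14 rose and 6, 5, 3, 0 and 5 fell adjusted over the list alone. Camera gave them adjusted p from 0.000463 to 0.0192, and adjusted p from 0.343 to 0.559 with an estimated correlation. HERPUD1 (1.53 ± 0.20) and HMOX1 (4.87 ± 0.35) rose. Interferon-stimulated genes did not pass as a set with both drugs (camera adjusted p = 0.284; with fry it passed as lower, adjusted p = 0.000176). Of 41, 16 fell, 8 rose and 17 did not pass (16 fell and 9 rose adjusted over the list alone). ATF4 targets did not pass either (camera adjusted p = 0.07), although CHAC1 (5.80 ± 0.50) and ATF3 (5.76 ± 0.20) rose. Of 35, 13 rose, 5 fell and 17 did not pass (the same adjusted over the list alone). Heat shock genes did not pass (camera adjusted p = 0.222), and of 23, 9 fell, 5 rose and 9 did not pass (9 fell and 6 rose adjusted over the list alone). With each array centred on its median the median gene lay at -0.17, 2503 genes were higher and 7519 lower (25% higher, against 50.3%), and the ATF4 target list passed as higher (adjusted p = 0.00638), though 12 members rose and 11 fell and the median of 0.17 became 0.02. It also passed without DMSO replicate 2 (0.0229), without combination replicate 1 (0.0392) and with fry (0.00392). Heat shock genes passed as lower with fry (adjusted p = 0.000106). The chaperone call was lost without genes below the lower tertile (adjusted p = 0.0741), and without genes below the median so were the chaperone, fatty acid synthesis, histone, antigen presentation and immediate early calls (0.0633 to 0.266).

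**Figure D1:**
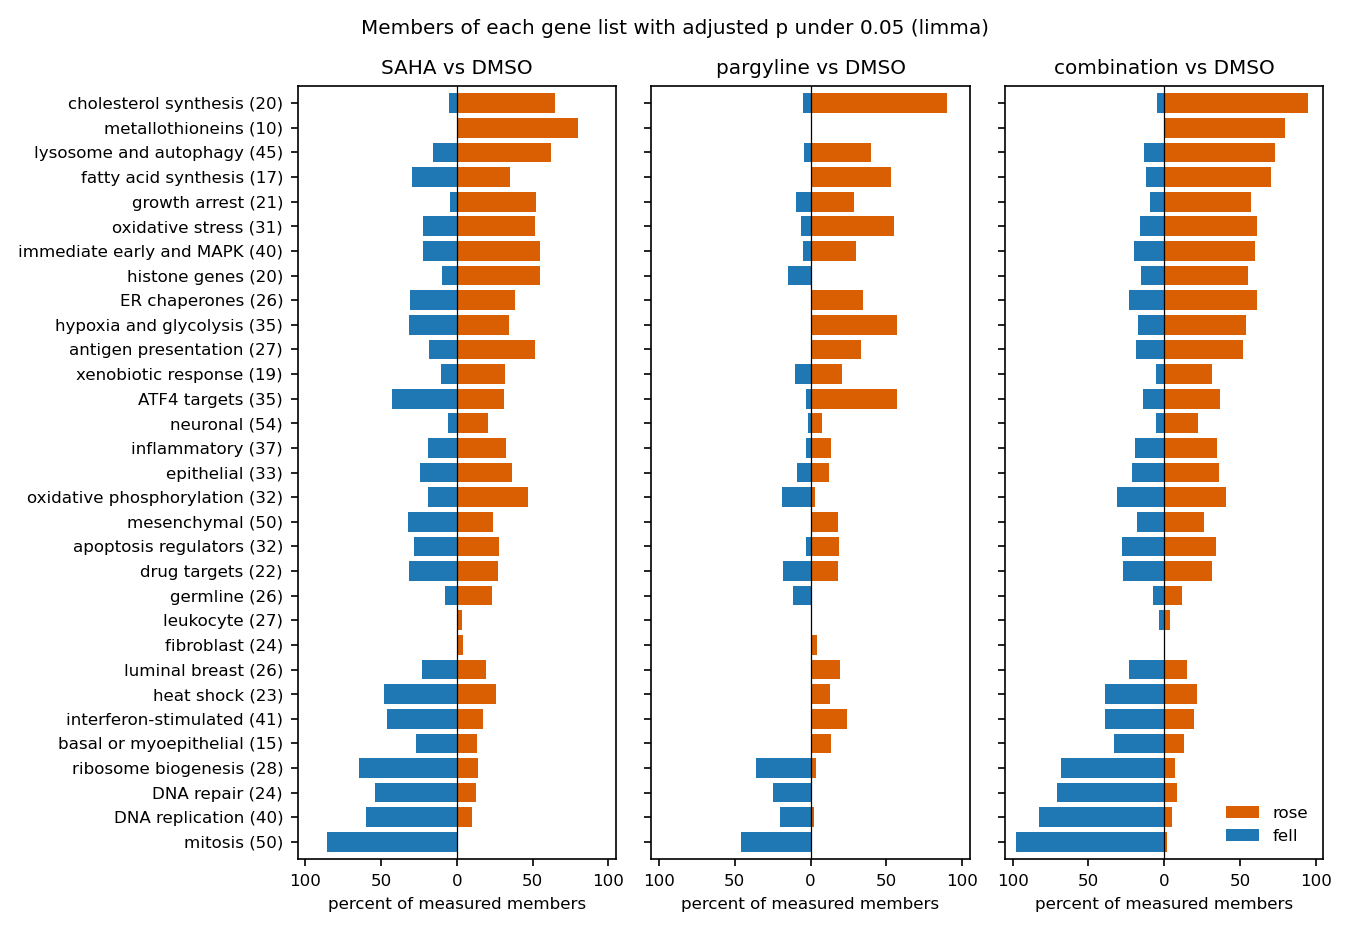
Percent of the measured members of each of the 31 gene lists (member number in brackets) that rose or fell against DMSO with adjusted p under 0.05 in limma, for SAHA, pargyline and both drugs. Mitosis genes fell in all 3 comparisons (43, 23 and 49 of 50), and cholesterol synthesis genes rose in all 3 (13, 18 and 19 of 20).

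The genes for the drugs' own targets also changed. HDAC5 rose with SAHA (3.04 ± 0.19), with pargyline (1.28 ± 0.19) and with both (3.63 ± 0.19), HDAC3 rose with SAHA (1.28 ± 0.09) and with both (0.95 ± 0.09), and HDAC7 fell with SAHA (-3.07 ± 0.41) and with both (-3.07 ± 0.41). KDM1A fell with pargyline (-0.44 ± 0.09) and gave 0.21 ± 0.09 with SAHA and -0.20 ± 0.09 with both, which did not pass. MAOA rose with SAHA (1.2 ± 0.11), with both (1.49 ± 0.11) and with pargyline (0.42 ± 0.11), the last lost with quantile normalization (adjusted p = 0.0555), with array centring (adjusted p = 0.057) and with the mean of all probe sets (adjusted p = 0.0713), and without DMSO replicate 1 or 2 or pargyline replicate 1 or 3 (adjusted p from 0.0736 to 0.119). Smaller changes passed but rested on single arrays and settings. HDAC1 with SAHA (0.16 ± 0.04) was lost with array centring and without DMSO replicate 2 or SAHA replicate 1 (adjusted p from 0.0524 to 0.363), and HDAC4 with SAHA (-0.46 ± 0.16) with quantile normalization and without any 1 DMSO array or SAHA replicate 1 or 2 (0.062 to 0.131). HDAC6 with pargyline (-0.31 ± 0.08) was lost with the mean of all probe sets (-0.10; its further probe sets gave 0.00 and 0.01), with a trended and robust prior and without any 1 DMSO array or pargyline replicate 1 or 2 (0.0524 to 0.097), and HDAC9 with both (1.08 ± 0.37) with quantile normalization and without any 1 DMSO array or combination replicate 2 or 3 (0.0545 to 0.133). The log2 changes with SAHA, pargyline and both that did not pass were 0.12 ± 0.07, -0.04 ± 0.07 and -0.15 ± 0.07 for HDAC2, 0.09 ± 0.07, -0.04 ± 0.07 and 0.08 ± 0.07 for HDAC11, and 0.14 ± 0.08, -0.08 ± 0.08 and 0.02 ± 0.08 for MAOB, and HDAC7 with pargyline gave -1.10 ± 0.41 (adjusted p = 0.105), but passed at -0.50 without pargyline replicate 1 (adjusted p = 0.0188). With array centring HDAC1 (-0.18), HDAC2 (-0.17), HDAC3 (-0.34) and HDAC7 (-1.23) passed as lower with pargyline (adjusted p from 0.0212 to 0.0387), and HDAC1 (-0.17), HDAC2 (-0.31) and KDM1A (-0.36) with both (adjusted p from 0.00171 to 0.0117). With array weights HDAC2 (-0.14) and KDM1A (-0.24) passed as lower and HDAC6 (0.23) as higher with both (adjusted p from 0.0124 to 0.0445), and HDAC9 passed as higher with SAHA (1.25, adjusted p = 0.0203) without SAHA replicate 1. HDAC8 and HDAC10 were not analysed here. Over the list of 22 targets and partners, the set did not pass in camera with SAHA (adjusted p = 0.65), pargyline (0.427) or both (0.815), and 6, 4 and 7 members rose and 7, 4 and 6 fell (adjusted over the list alone, 6, 4 and 7 rose and 7, 7 and 6 fell). With fry, which asks whether a list moves on balance one way, the set passed as higher with SAHA (adjusted p = 0.000535) and with both (0.0466) and as lower with pargyline (0.00393). Against SAHA, both drugs gave lower KDM1A (by a log2 difference of -0.41 ± 0.09), HDAC1 (-0.17 ± 0.04), HDAC2 (-0.27 ± 0.07) and HDAC3 (-0.33 ± 0.09). The HDAC1 call was lost with a trended and robust prior and without SAHA replicate 1 or 3 or combination replicate 2, the HDAC2 call without SAHA replicate 3 or combination replicate 1 or 2, and the HDAC3 call without SAHA replicate 1 or 2 or any 1 combination array (adjusted p from 0.0517 to 0.128). HDAC4 (0.47 ± 0.16) and HDAC5 (0.59 ± 0.19) passed there as higher only with the replicate block, with array weights and, in turn, without SAHA replicate 3 and with that prior (adjusted p from 0.0123 to 0.0435), and MAOA (0.29 ± 0.11) only with array weights (0.0402). None of these genes passed in the interaction.

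The combination was compared with SAHA to ask what pargyline added to SAHA. Adding pargyline raised 943 genes and lowered 1042, and 131 rose and 98 fell by at least 2-fold. S100P rose by 3.77 ± 0.47 (SE, n = 3 per group), ANGPTL4 by 3.34 ± 0.28 and CHAC1, which degrades glutathione, by 3.30 ± 0.50. The transcription factor gene KLF2 (-4.59 ± 0.30), SREBF1 (-2.18 ± 0.26) and the mitotic gene HMMR (-2.03 ± 0.34) fell. HMOX1 (2.67 ± 0.35) and NR4A1 (2.58 ± 0.56) also rose, the latter not without combination replicate 2 (adjusted p = 0.0525), and TCTA (-1.99 ± 0.19) and C11orf71 (-1.96 ± 0.36) also fell. Adjusted p among these 10 genes ran from 0.000284 to 0.0127 in limma.

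Of 50 mitosis genes, 40 fell, 0 rose and 10 did not pass (46 fell and 2 rose adjusted over the list alone). These genes gave adjusted p = 2.52e-17 in camera, and adjusted p = 0.254 with an estimated correlation. NCAPH (-1.59 ± 0.29) and CCNA2 (-1.41 ± 0.17) fell. Of 40 DNA replication genes, 24 fell, 0 rose and 16 did not pass (30 fell and 0 rose adjusted over the list alone). These genes gave adjusted p = 1.45e-12 in camera, and adjusted p = 0.254 with an estimated correlation. POLA2 (-1.39 ± 0.20) fell. Of 24 DNA repair genes, 13 fell, 0 rose and 11 did not pass (15 fell and 0 rose adjusted over the list alone). This set gave adjusted p = 1.11e-06 in camera, and adjusted p = 0.176 with an estimated correlation. Of 35 ATF4 targets, 17 rose, 1 fell and 17 did not pass (23 rose and 1 fell adjusted over the list alone). This set gave adjusted p = 8.18e-12 in camera, and adjusted p = 0.195 with an estimated correlation. DDIT3 (2.26 ± 0.33) and the asparagine synthetase gene ASNS (1.55 ± 0.22) rose. Cholesterol synthesis genes (of 20, 13 rose and 1 fell), fatty acid synthesis genes (of 17, 11 rose and 1 fell) and hypoxia and glycolysis genes (of 35, 19 rose and 0 fell) were higher as sets. Adjusted over the list alone, in this order, 15, 13 and 21 rose and 1, 1 and 2 fell. These sets gave adjusted p from 2.23e-10 to 1.83e-08 in camera, and adjusted p from 0.105 to 0.195 with an estimated correlation. HMGCS1 rose by 2.00 ± 0.29, FASN by 2.09 ± 0.32 (0.16 from its further probe set) and P4HA1 by 1.29 ± 0.10.

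With pargyline added to SAHA, 5 more lists passed. Endoplasmic reticulum chaperone genes (of 26, 12 rose and 1 fell), lysosome and autophagy genes (of 45, 17 rose and 2 fell), oxidative stress genes (of 31, 8 rose and 2 fell), interferon-stimulated genes (of 41, 4 rose and 0 fell) and antigen presentation genes (of 27, 5 rose and 0 fell) were higher as sets. In the same order, 15, 22, 8, 4 and 6 rose and 3, 3, 3, 0 and 0 fell adjusted over the list alone. Camera gave them adjusted p from 6.09e-08 to 0.00837, and adjusted p from 0.105 to 0.489 with an estimated correlation. HERPUD1 rose by 1.12 ± 0.20, SQSTM1, an autophagy receptor, by 0.82 ± 0.10, IFI35 by 2.31 ± 0.14 and MICA by 0.43 ± 0.09. The interferon-stimulated call was lost without combination replicate 3 (adjusted p = 0.0585), and the oxidative stress call with fry (0.0524). The interferon median of 0.04 became -0.02 with array centring, which gave 715 higher and 1347 lower genes (34.7% higher, against 47.5%). Without combination replicate 2 the counts were 607 higher and 632 lower, in a fit of the SAHA and combination arrays alone 616 and 614, and with replicate number as a block 1169 and 1250.

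The combination was compared with pargyline to ask what SAHA added to pargyline, and 2856 genes were higher and 2826 lower. ABAT rose by 8.03 ± 0.15 (SE, n = 3 per group), HPCAL4 by 7.34 ± 0.10, NR4A1 by 6.77 ± 0.56, CYFIP2, a regulator of the actin cytoskeleton, by 6.71 ± 0.27 and TEX14 by 6.62 ± 0.21. SERPINH1 (-8.23 ± 0.26), IFIT3 (-6.72 ± 0.15), LPXN (-6.66 ± 0.28), SLCO4A1 (-6.62 ± 0.22) and IL7R (-6.49 ± 0.65) fell. Adjusted p among these 10 genes ran from 8.12e-11 to 2.04e-05 in limma. Mitosis genes (of 50, 48 fell and 1 rose), DNA replication genes (of 40, 34 fell and 3 rose), DNA repair genes (of 24, 11 fell and 2 rose), ribosome biogenesis genes (of 28, 17 fell and 5 rose) and interferon-stimulated genes (of 41, 22 fell and 6 rose) were lower as sets. Adjusted over the list alone, in this order, 48, 34, 11, 17 and 24 fell and 1, 3, 2, 5 and 6 rose. These sets gave adjusted p from 6.73e-14 to 0.0262 in camera, and adjusted p from 0.486 to 0.558 with an estimated correlation. Histone genes (of 20, 12 rose and 3 fell), growth arrest genes (of 21, 10 rose and 3 fell), metallothionein and zinc response genes (of 10, 8 rose and 0 fell) and lysosome and autophagy genes (of 45, 31 rose and 8 fell) were higher as sets. In the same order, 12, 10, 9 and 32 rose and 4, 3, 0 and 8 fell adjusted over the list alone. Camera gave them adjusted p from 0.000153 to 0.0262, and adjusted p from 0.486 to 0.558 with an estimated correlation. The DNA repair call was lost with quantile normalization (adjusted p = 0.054). Without genes below the lower tertile the DNA repair, growth arrest and ribosome biogenesis calls were lost (adjusted p from 0.0541 to 0.0696), and without genes below the median also the histone and interferon-stimulated calls (0.0912 to 0.258).

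SAHA and pargyline were compared directly to ask where the single drugs differed, and 2803 genes were higher and 2718 lower with SAHA. TXNIP was higher with SAHA by a log2 difference of 5.10 ± 0.19 (SE, n = 3 per group), HLA-DMB by 5.23 ± 0.14 and SYT11 by 5.28 ± 0.13. IFIT3 (-7.17 ± 0.15), CASP4 (-5.28 ± 0.28) and ABCC3 (-5.84 ± 0.36) were lower with SAHA, and members counted as fallen here were lower with SAHA than with pargyline. Interferon-stimulated genes (of 41, 22 fell and 6 rose), ATF4 targets (of 35, 22 fell and 3 rose), hypoxia and glycolysis genes (of 35, 19 fell and 8 rose) and cholesterol synthesis genes (of 20, 14 fell and 4 rose) were lower as sets. Adjusted over the list alone, in this order, 23, 22, 20 and 14 fell and 6, 3, 8 and 4 rose. These sets gave adjusted p from 5.05e-05 to 0.0151 in camera, and adjusted p from 0.202 to 0.651 with an estimated correlation. Heat shock genes (of 23, 12 fell and 4 rose), mitosis genes (of 50, 27 fell and 3 rose), DNA replication genes (of 40, 20 fell and 5 rose) and ribosome biogenesis genes (of 28, 16 fell and 5 rose) were lower as sets. In the same order, 13, 29, 20 and 17 fell and 4, 3, 5 and 6 rose adjusted over the list alone. Camera gave them adjusted p from 5.05e-05 to 0.0167, and adjusted p = 0.651 for each with an estimated correlation. Histone genes (of 20, 11 rose and 2 fell), metallothionein and zinc response genes (of 10, 9 rose and 0 fell), lysosome and autophagy genes (of 45, 27 rose and 9 fell) and oxidative phosphorylation genes (of 32, 19 rose and 4 fell) were higher as sets. Adjusted over the list alone, in this order, 11, 9, 27 and 19 rose and 2, 0, 9 and 5 fell. These sets gave adjusted p from 0.00094 to 0.0345 in camera, and adjusted p = 0.651 for each with an estimated correlation. The lysosome and oxidative phosphorylation calls were lost with array centring (adjusted p = 0.0691 and 0.0502), with array weights (0.0504 and 0.0554), without SAHA replicate 1 (0.0807 and 0.0535) and without pargyline replicate 2 (0.0915 and 0.0887). Without genes below the lower tertile these calls and those on DNA replication, cholesterol synthesis, heat shock, hypoxia and ribosome biogenesis were lost (adjusted p from 0.0933 to 0.107), and without genes below the median also the histone and interferon-stimulated calls (0.102 to 0.136).

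The single drugs moved many of the same genes. Of the 1014 genes that rose with pargyline, 565 also rose with SAHA, where 233 would be shared if the calls were independent, and 219 fell with SAHA (235 if independent). Of the 891 genes that fell with pargyline, 510 also fell with SAHA (206 if independent) and 198 rose (205 if independent). Both comparisons share DMSO arrays. In 100 simulations of unchanged groups at most 2 genes were shared, which cannot size the effect on the overlap. Across all genes, not independent replicates, single-drug changes correlated with r = 0.229 (Spearman 0.223). Simulation gave 0.5 (0.443), so r does not show a shared effect. The covariance was 0.0792 (simulated 0.00879). Each drug's effect could also be compared without and with the other, with no shared arrays: across genes, SAHA against DMSO and the combination against pargyline correlated with r = 0.934 (Spearman 0.856), and pargyline against DMSO and the combination against SAHA with r = 0.498 (Spearman 0.469). Of the genes that rose with pargyline alone 386 also rose when it was added to SAHA (79.9 if independent), and of those that fell 414 also fell (77.6 if independent).

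**Figure D2:**
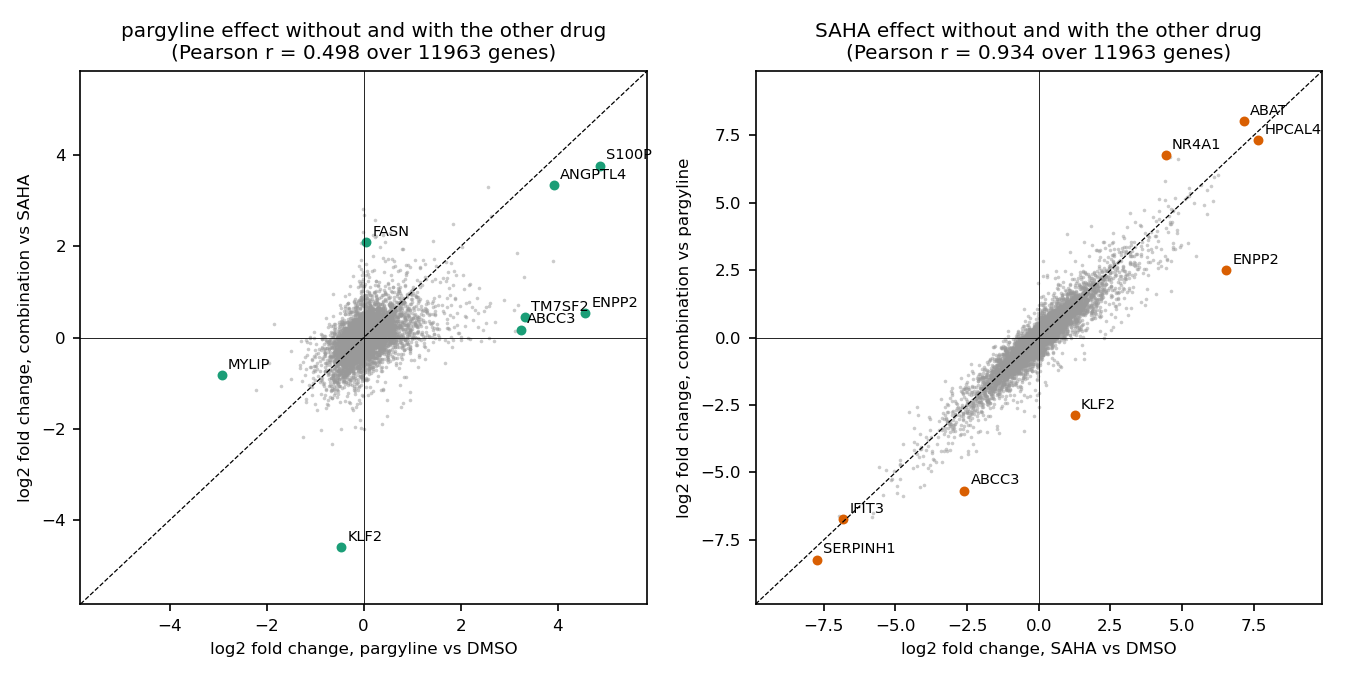
Log2 fold change of each gene for a drug alone (x axis) and for the same drug added to the other one (y axis), for pargyline (left) and SAHA (right), with a dashed line of equality and example genes named. The pargyline effects correlated with r = 0.498 and the SAHA effects with r = 0.934 across 11963 genes.

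The interaction, the effect of the combination minus the sum of the single-drug effects on the log2 scale, asked where the drugs did more or less together than their sum. It was above 0 for 153 genes and below 0 for 292, of which 33 and 110 departed by at least 2-fold. KLF2 averaged 9.29 ± 0.03 with DMSO, 10.55 ± 0.60 with SAHA, 8.83 ± 0.27 with pargyline and 5.96 ± 0.45 with both (log2, SD, n = 3), an interaction of -4.13 ± 0.43 (SE). ENPP2 rose by 6.55 with SAHA, 4.57 with pargyline and 7.09 with both (-4.03 ± 0.38), and TM7SF2 by 4.61, 3.33 and 5.06 (-2.88 ± 0.35). ABCC3 (-3.07 ± 0.50) and the sulfotransferase gene SULT1C2 (-2.98 ± 0.11) were high with pargyline alone, at means of 8.07 ± 0.13 and 7.17 ± 0.11, and low with both, at 2.40 ± 0.50 and 3.70 ± 0.07. ABCC3 also averaged 2.23 with SAHA, and 2.23 is the lower quartile of all values, so the floor limits its interaction.

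Above the sum were CYFIP2 (2.14 ± 0.38), MYLIP (2.11 ± 0.22), DDIT3, which encodes the stress response factor CHOP (2.07 ± 0.46), FASN, the fatty acid synthase (2.04 ± 0.45) and TEX14 (1.77 ± 0.30), which lay near the floor with DMSO (2.25) and pargyline (2.19). DDIT3 averaged 8.21 ± 0.38, 8.49 ± 0.07, 8.40 ± 0.21 and 10.74 ± 0.75 in the 4 groups, and FASN 10.80 ± 0.33, 10.78 ± 0.47, 10.85 ± 0.45 and 12.87 ± 0.41. Adjusted p among these 10 genes ran from 3.46e-06 to 0.0426 in limma. The DDIT3 call was lost without any 1 array other than DMSO replicate 3 or combination replicate 3 (adjusted p from 0.05 to 0.106). The FASN call was lost without any 1 array other than SAHA, pargyline or combination replicate 3 (adjusted p from 0.0656 to 0.0952) and with quantile normalization (adjusted p = 0.0502), and the further FASN probe set gave 0.13. CDKN1A gave -1.0 ± 0.35 and did not pass (adjusted p = 0.166).

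By list, the interaction was below 0 for 6 lists and above 0 for 1. The median over DNA replication genes was -0.24 (camera adjusted p = 0.000591, and adjusted p = 0.822 with an estimated correlation), and over mitosis genes -0.22 (camera adjusted p = 0.0358, and adjusted p = 0.835 with an estimated correlation). Cholesterol synthesis genes had a median of -0.32 (camera adjusted p = 0.00292, and adjusted p = 0.8 with an estimated correlation), and oxidative stress genes of -0.18 (camera adjusted p = 0.00058, and adjusted p = 0.788 with an estimated correlation). Hypoxia and glycolysis genes had a median of -0.07, or 0.00 with array centring (camera adjusted p = 0.00852, and adjusted p = 0.8 with an estimated correlation). For luminal breast genes it was -0.14 (camera adjusted p = 0.00852, and adjusted p = 0.24 with an estimated correlation), and for ribosome biogenesis genes 0.15 (camera adjusted p = 0.00292, and adjusted p = 0.788 with an estimated correlation).

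Few list members passed the interaction test on their own. Above and below 0 lay 1 and 3 of the DNA replication genes, 1 and 0 of the mitosis genes, 0 and 3 of the cholesterol synthesis genes and 0 and 5 of the oxidative stress genes. For the hypoxia, luminal and ribosome biogenesis genes these counts were 0 and 4, 0 and 1, and 2 and 1. Adjusted over the list alone, in the same order, they were 2 and 8, 1 and 0, 0 and 4, 0 and 10, 0 and 8, 0 and 1, 2 and 1. AKR1C3 (-2.19 ± 0.12) and AKR1C2 (-1.85 ± 0.29), whose probe sets can bind each other's transcripts, were below the sum. With fry the DNA replication (adjusted p = 0.3), mitosis (0.532), cholesterol (0.171), hypoxia (0.143) and ribosome biogenesis (0.171) lists did not pass. The mitosis call was also lost with the mean of all probe sets (adjusted p = 0.0536), without genes below the lower tertile (0.0662) and without DMSO replicate 2, SAHA replicate 1 or 3, pargyline replicate 1 or combination replicate 2 (adjusted p from 0.059 to 0.465). The hypoxia call was lost without SAHA replicate 1 or pargyline replicate 1 or 3 (0.0674 to 0.141), and without genes below the median (0.06), where the luminal call was lost too (0.0642), and the cholesterol call without combination replicate 3 (0.108). Array centring put the median interaction of all genes at 0.07 and gave 220 genes above and 215 below (50.6% above, against 34.4%). Above and below 0 lay 275 and 395 with replicate number as a block, and 446 and 633 with array weights. Counts above 0 became 87 without DMSO replicate 1, 78 without DMSO replicate 2, 90 without SAHA replicate 2, 99 without pargyline replicate 3, 86 without combination replicate 2 and 236 without combination replicate 3. Counts below 0 became 164 without DMSO replicate 1, 167 without DMSO replicate 2, 193 without SAHA replicate 1, 171 without SAHA replicate 2, 192 without combination replicate 1 and 160 without combination replicate 2.

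**Figure D3:**
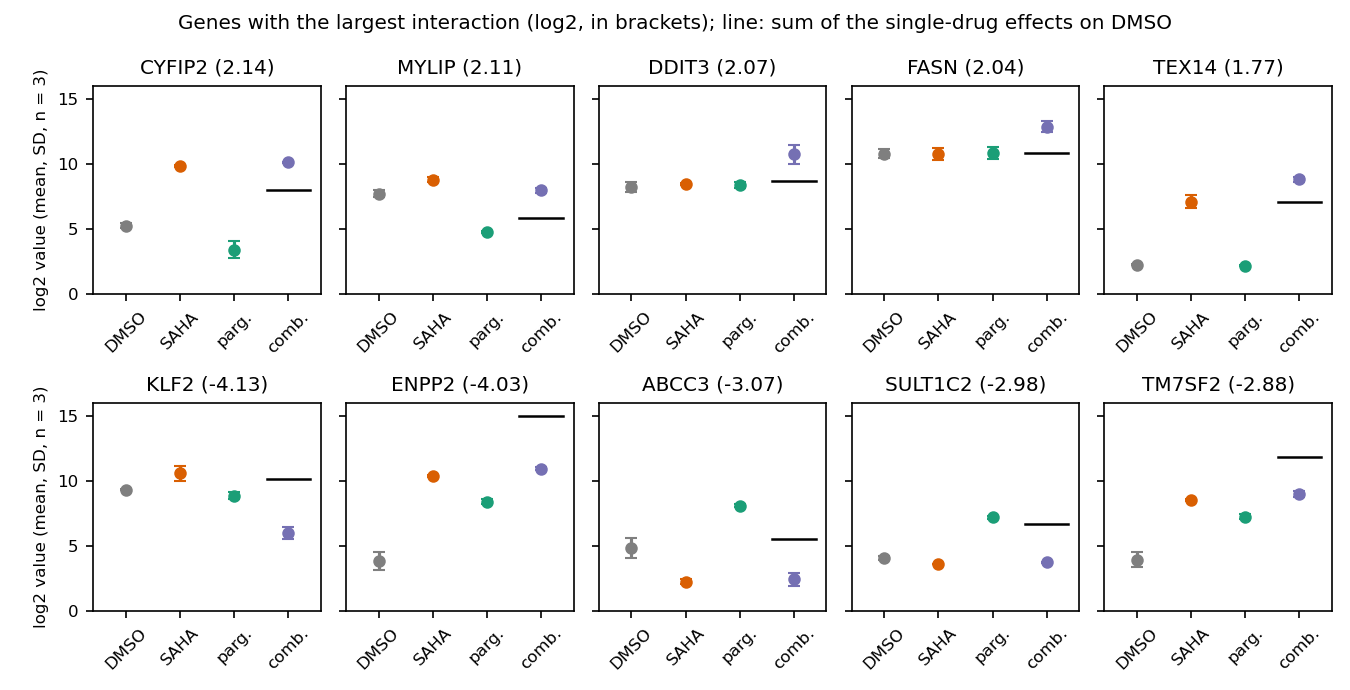
Group means and SD (n = 3) of the log2 values of the 10 genes with the largest interaction, with the interaction in brackets and a line at the level that the single-drug effects would sum to. KLF2 lies below that line with both drugs and FASN above it.

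**Figure D4:**
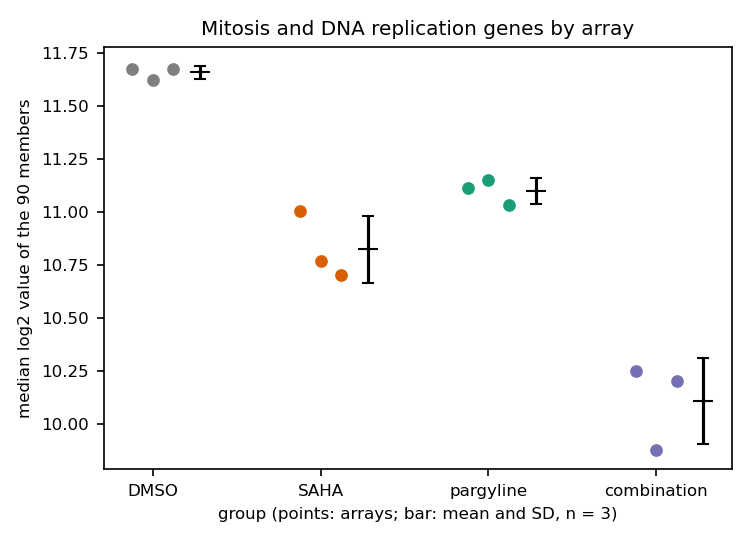
Median log2 value of the 90 measured mitosis and DNA replication genes on each array (points), with the group mean and SD (n = 3). The group means were 11.66 with DMSO, 10.82 with SAHA, 11.10 with pargyline and 10.11 with both drugs.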

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

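The tests of scaling with quantile normalization and median centring and the test of spread between cultures were chosen after the results were seen. The test without the arrays numbered 3 and the one that rearranges residuals were added after the data had been examined, but before their own results were seen; the other tests were set before.

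Of the 445 genes whose pargyline effect with SAHA differed from that without it in limma's interaction test, 10 are given, the 5 largest each way. It was higher with SAHA for CYFIP2 (2.14), MYLIP (2.11), DDIT3 (2.07), FASN (2.04) and TEX14 (1.77), and lower for KLF2 (-4.13), ENPP2 (-4.03), ABCC3 (-3.07), SULT1C2 (-2.98) and TM7SF2 (-2.88). Of these, DDIT3 and FASN rest on single arrays: the DDIT3 call was lost without any 1 array other than DMSO or combination replicate 3 (adjusted p up to 0.106), and the FASN call without any 1 array other than SAHA, pargyline or combination replicate 3 (adjusted p up to 0.0952). In 7 lists the median interaction differed from that of other genes by camera: DNA replication (-0.24), mitosis (-0.22), cholesterol synthesis (-0.32), oxidative stress (-0.18), hypoxia and glycolysis (-0.075), luminal breast genes (-0.14) and ribosome biogenesis (0.15). None of the 7 passed with an estimated correlation, where the lowest adjusted p was 0.24.

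Probe sets that the gene comparisons do not use also changed. Of 1043 probe sets listed for several genes, 402 passed with SAHA, 118 with pargyline and 395 with both drugs against DMSO. Of 2108 listed for no gene, 437, 128 and 474 passed. These genes were not analysed here.

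Pargyline alone gave 231 rises and 42 falls of at least 2-fold, a ratio of 5.5. If a difference in scaling between arrays were the cause, the ratio should fall under 1.5 with another scaling. It was 4.35 with quantile normalization (3.79 to 4.77 with each array left out) and 2.65 with each array centred on its median (180 rises, 68 falls; 2.22 to 2.77 with each array left out), which argues against scaling as the whole cause, though the size of the ratio depends on it. Poly-A spike-ins read -0.28 against DMSO, and scaling to them would add to every change, so it tests nothing here. If falls were hidden near the floor of the scale, the excess should vanish among the 5928 genes above the median in DMSO; the ratio there was 3.32 (93 rises, 28 falls; 3 to 4.4 with each array left out), which argues against the floor as the whole cause. At any fold quantile normalization gave 922 genes higher and 986 lower. Median centring, which puts the median gene at -0.15, gave 872 and 6168, so the balance depends on centring. The excess of strong rises may be a response of the cells, a hypothesis found and tested on the same data.

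Over the 90 measured mitosis and DNA replication genes the median interaction was -0.23 (95% bootstrap interval over genes -0.33 to -0.19, with 74 below 0). On these arrays they thus fell further with both drugs than the single-drug effects add up to. The arrays numbered 3 do not account for it, since without those 4 arrays the median was -0.32 (-0.39 to -0.24), nor does saturation of bright probe sets, since the dimmer 45 genes gave -0.18 (-0.41 to -0.07), nor scaling as the whole cause, since it was -0.23 with quantile normalization (-0.33 to -0.18) and -0.16 with median centring (-0.25 to -0.11). Spread between cultures that these genes share stays open: the array medians averaged 11.66 with DMSO, 10.82 with SAHA, 11.10 with pargyline and 10.11 with both, an interaction of -0.15 with a standard error of 0.15 over arrays, or -1.01 standard errors. With each array left out in turn the median over genes ran from -0.35 to -0.12. A greater than additive fall of these genes is thus a hypothesis that the spread between 3 cultures per group may account for.

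For pairs of groups, 10 splits of 6 arrays are too few for a share under 0.05. For SAHA, pargyline and the combination against DMSO, the real split gave 5522, 1905 and 5775 genes and the highest other 0, 1 and 0. For the combination against SAHA and pargyline, and SAHA against pargyline, these were 1985, 5682 and 5521, and 11, 1 and 0. Lists, in this order, numbered 14, 20, 15, 12, 9 and 12, and 14, 16, 13, 14, 9 and 12 in the highest other. As many passed in 2, 1, 1, 4, 2 and 2 of the 10 splits, so chance is not excluded for pairwise list calls. Equally numbered arrays correlated (r over 0.1) in 13 of 18 pairs. Of 12 arrays, 10 correlated best with their own number in every other group. All 3 pairs did for DMSO with pargyline and SAHA with combination. There the 3 other splits that part them gave at most 1 and 0 genes, and 12 and 14 lists. The remaining splits part 1 pair.

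For the interaction, 2 of 100 splits of all arrays, the real one included, gave as many as 445 genes, and 2 of 100 splits within arrays with and without SAHA. These splits leave open whether chance can be excluded, because they put arrays given different drugs into 1 group: the median residual SD was 0.0992 in the real split, and 0.219 and 0.133 at the median of the others. The highest others gave 1959 and 3009 genes, several times the real count, which points to a structure of the samples. The 3009 came from exchanging all SAHA and combination arrays, so that the contrast measures the pargyline effect with and without SAHA together. The 1959 came from a split with 5 arrays given SAHA on 1 side, but 3 further splits with 5 gave 0 to 8 genes, so its source was not found. For lists, 72 and 67 of 100 splits gave at least the real 7 (highest 17 and 20), with the same limit.

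Both drug effects were kept and residuals of a model without interaction put in other orders of the arrays. Of 100 arrangements, the real one included, 1 gave as many as 445 genes (highest other 14). Other orders turn any interaction into spread within groups, so chance stays open for the gene count. For lists, 38 gave at least the real 7 (highest other 14), so chance is not excluded there.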

How the results depend on the processing

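The alternative without the 4 arrays numbered 3 was added after the arrays had been compared, and the others were set before; the cause of the moved values was not tested except where the setting itself makes it plain (fewer genes or arrays tested, or a stricter threshold). Medians near 0 of 7 lists that passed changed sign with median centring, as given with the lists. The 4 arrays numbered 3 moved no count by more than 1.5 times. Named genes were followed with both normalizations, the mean of probe sets, the block, array weights, the prior and each array left out. Of 779 named values that passed, 692 passed under all of these. Of 9660 values under them 9235 still passed, 425 did not (370 with an array left out) and 0 reversed. Another 24 values that had not passed did so under one of them. The correlation of the single-drug changes ran from 0.214 to 0.256 with each array left out (jackknife SE 0.0322). Signal over background limits both ends: 2.23 was the lower quartile of all values, and 61 passing genes rose from below it with SAHA and 30 fell to below it, against 9 and 4 with pargyline and 80 and 33 with both, so the background limits those fold changes. Group values did not overlap for 52.9% of genes with SAHA, 30.8% with pargyline and 66.0% with both, where chance gives 10%.

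For genes higher and lower, an added change of at least 2-fold left 1123 and 1047 (SAHA against DMSO), 231 and 42 (pargyline against DMSO), 1286 and 1168 (combination against DMSO), 131 and 98 (combination against SAHA), 1071 and 1098 (combination against pargyline), 1009 and 1060 (SAHA against pargyline) and 33 and 110 (interaction). An adjusted p under 0.01 left 592 and 355 for pargyline against DMSO, 452 and 499 for the combination against SAHA, and 28 and 64 for the interaction. Every probe set on its own gave 4288 and 4532 for SAHA, 4581 and 4722 for the combination against DMSO, 1478 higher for the combination against SAHA, 4517 and 4583 for the combination against pargyline, and 4376 and 4451 for SAHA against pargyline. Median centring gave 6168 lower with pargyline and 7519 lower with the combination against DMSO. Array weights gave 1466 lower with pargyline, and 446 and 633 for the interaction, and the replicate block 275 higher for the interaction. A fit of the compared groups alone gave 616 and 614 for the combination against SAHA.

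Only 1 list passed with an estimated correlation, as higher with pargyline against DMSO. With fry 16 were higher for SAHA, 17 higher and 7 lower for the combination against DMSO, 12 and 11 for the combination against pargyline, 12 and 14 for SAHA against pargyline, and 0 and 3 for the interaction. Without genes below the lower tertile 3 were lower for SAHA, 3 lower for the combination against pargyline, and 2 higher and 3 lower for SAHA against pargyline. Without genes below the median 4 were higher and 3 lower for SAHA, 6 higher for the combination against DMSO, 2 and 2 for the combination against pargyline, and 1 and 2 for SAHA against pargyline, and the correlation of the single-drug changes was 0.264. For SAHA 3 were lower with quantile normalization, 3 with median centring and 3 with array weights. For SAHA against pargyline 2 were higher with median centring and 2 with array weights, and for the interaction 11 lower with median centring.

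With each array left out in turn, pargyline lowered from 479 to 859 genes, the lowest without DMSO replicate 2. The combination against SAHA gave 607 to 926 higher and 632 to 1069 lower, the lowest without combination replicate 2. The interaction gave 78 to 236 genes above 0, from without DMSO replicate 2 to without combination replicate 3, and 160 to 420 below 0, the lowest without combination replicate 2. Lists lower with SAHA ran from 3 to 6, and lists higher for SAHA against pargyline from 2 to 4.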

Other observations

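No test in this part was chosen after the results were seen. Neuronal genes did not pass as a set with SAHA (camera adjusted p = 0.11), but a few rose far. The set passed as higher with fry (adjusted p = 0.000283), which does not set it against other genes. Of 54, 9 of which lay above the median over genes in DMSO, 11 rose, 3 fell and 40 did not pass (10 rose and 3 fell adjusted over the list alone). The synaptotagmin gene SYT11 (5.27 ± 0.13, n = 3 per group), MAP2 (5.18 ± 0.16) and the tau gene MAPT (2.40 ± 0.18) were among the rises. With both drugs the neuronal median was -0.01 and the mean 0.59, and 12 rose, 3 fell and 39 did not pass (11 rose and 3 fell adjusted over the list alone) (camera adjusted p = 0.26; adjusted p = 0.000176 with fry). With pargyline 4 rose, 1 fell and 49 did not pass (3 rose and 0 fell adjusted over the list alone) (camera adjusted p = 0.607). Of 26 germline genes, 6 rose, 2 fell and 18 did not pass (the same adjusted over the list alone) with SAHA (camera adjusted p = 0.425). The melanoma antigen gene MAGEB2 (4.6 ± 0.22) rose and MAGEC1 (-1.31 ± 0.12) fell, and such probe sets can bind transcripts of relatives.

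Epithelial, mesenchymal, luminal and basal genes moved both ways with SAHA, and none of these lists passed in camera. With fry the epithelial (adjusted p = 0.000847), germline (0.0191), inflammatory (0.0391), xenobiotic response (0.0159), oxidative phosphorylation (0.00934) and hypoxia and glycolysis lists (0.00762) passed as higher with SAHA, and the basal or myoepithelial list as lower (0.00588). Of 33 epithelial genes, 12 rose, 8 fell and 13 did not pass (the same adjusted over the list alone) (camera adjusted p = 0.495), with rises in JUP (2.79 ± 0.29) and KRT19 (2.76 ± 0.14) and a fall in PKP3, given above. Of 50 mesenchymal genes, 16 fell, 12 rose and 22 did not pass (the same adjusted over the list alone) (camera adjusted p = 0.668), with falls in the urokinase receptor gene PLAUR (-3.49 ± 0.21) and in CD44 (-2.11 ± 0.14). Of 26 luminal genes, 6 fell, 5 rose and 15 did not pass (the same adjusted over the list alone) (camera adjusted p = 0.882), with a fall in the transcription factor gene GATA3 (-2.96 ± 0.27). Of 15 basal or myoepithelial genes, 4 fell, 2 rose and 9 did not pass (the same adjusted over the list alone) (camera adjusted p = 0.63), with a median of 0.00 and a mean of -0.22.

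With pargyline, 4 further lists passed. Mesenchymal genes (of 50, 9 rose and 0 fell), luminal breast genes (of 26, 5 rose and 0 fell) and inflammatory genes (of 37, 5 rose and 1 fell) were higher as sets. In the same order, 10, 5 and 5 rose and 1, 0 and 1 fell adjusted over the list alone. Camera gave them adjusted p from 0.0301 to 0.0366, and adjusted p from 0.0899 to 0.425 with an estimated correlation. LOX (1.64 ± 0.20), XBP1 (0.97 ± 0.10) and IL11 (1.22 ± 0.15) were among the rises. With median centring the medians of these 3 lists turned from 0.01, 0.03 and 0.04 to -0.12, -0.10 and -0.09, and 8 mesenchymal genes rose and 18 fell. The mesenchymal call was lost with quantile normalization (adjusted p = 0.0627) and without DMSO replicate 1 (0.0605) or pargyline replicate 3 (0.0699). The inflammatory call was lost without DMSO replicate 3 (0.0632) or pargyline replicate 2 (0.0841), with array weights (0.0847) and with fry (0.0549), and the luminal call without pargyline replicate 1 (0.0768) and with array weights (0.051). Of 32 oxidative phosphorylation genes, 6 fell, 1 rose and 25 did not pass (7 fell and 1 rose adjusted over the list alone) with pargyline. Camera gave adjusted p = 0.006, and 0.376 with an estimated correlation. This call was lost without pargyline replicate 2 (0.113). None of 10 metallothionein genes passed with pargyline, over all genes or adjusted over the list alone (camera adjusted p = 0.191, and 0.04 without pargyline replicate 2).

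With SAHA, 12 rose, 7 fell and 18 did not pass (the same adjusted over the list alone) of 37 inflammatory genes (camera adjusted p = 0.425). The chemokine gene CXCL8 (4.08 ± 0.31) rose, and NFKB1 (-4.36 ± 0.36) and LIF (-4.16 ± 0.62) fell. Of 32 apoptosis regulators, 9 rose, 9 fell and 14 did not pass (the same adjusted over the list alone) with SAHA (camera adjusted p = 0.935), with a median of 0.02 and a mean of -0.12. BID (-3.14 ± 0.21) fell and CASP9 (1.28 ± 0.15) rose. Of 19 xenobiotic response genes, 6 rose, 2 fell and 11 did not pass (the same adjusted over the list alone) (camera adjusted p = 0.547), with a rise in CYP1A1 (2.92 ± 0.34) and a fall in CYP1B1 (-1.41 ± 0.18). Of 32 oxidative phosphorylation genes, 15 rose, 6 fell and 11 did not pass (the same adjusted over the list alone) (camera adjusted p = 0.232), but 9 rose and 10 fell with array centring, where the median of 0.08 became -0.02. Of 35 ATF4 targets, 15 fell, 11 rose and 9 did not pass (the same adjusted over the list alone) (camera adjusted p = 0.633), with a median of 0.00 and a mean of 0.11; ATF3 (4.67 ± 0.20) rose and TRIB3 (-2.20 ± 0.31) fell. Of 17 fatty acid synthesis genes, 6 rose, 5 fell and 6 did not pass (7 rose and 5 fell adjusted over the list alone) (camera adjusted p = 0.919), with a median of -0.02 and a mean of -0.12 beside a test that ranked them upward. Of 35 hypoxia and glycolysis genes, 12 rose, 11 fell and 12 did not pass (12 rose and 12 fell adjusted over the list alone) (camera adjusted p = 0.608), and of 26 endoplasmic reticulum chaperone genes, 10 rose, 8 fell and 8 did not pass (the same adjusted over the list alone) (camera adjusted p = 0.65).

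Markers of other cell types were low in DMSO. Of 24 fibroblast genes, 9 of which are also in another list, 0 lay above the median over genes there, and the highest was COL1A1, at 6.22. With SAHA 1 rose, 0 fell and 23 did not pass (0 rose and 0 fell adjusted over the list alone) (camera adjusted p = 0.919), the 1 being PDGFRB (0.10 ± 0.03), and with pargyline 1 rose, 0 fell and 23 did not pass (the same adjusted over the list alone) (camera adjusted p = 0.464), the 1 being FBLN1 (1.55 ± 0.09), both named after their values were seen. Of 27 leukocyte genes 0 lay above the median over genes in DMSO, and the highest was LCP2, at 2.86. With SAHA 1 rose, 0 fell and 26 did not pass (the same adjusted over the list alone) (camera adjusted p = 0.919), and the 1 was the actin-binding gene CORO1A (5.86 ± 0.49, and 5.36 ± 0.49 with both drugs).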
